A study of Mus musculus with 39 samples.

How the data were processed

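RNA was sequenced from micropunches of the basolateral amygdala (BLA) and the nucleus accumbens (NAc) of mice that were wild type or carried a gene-trap allele of Lmo4 (Lmo4gt/+). Per the labels' protocols, frozen brains were sectioned at 300 µm, the regions were punched out, RNA was extracted and treated with DNase, polyA RNA was enriched, and libraries were made for an Illumina NextSeq. The deposited files hold whole-number counts of reads per Ensembl gene and library, with no normalization. Per the submitters' processing notes, HISAT2 (no version given), HTSeq 0.11.1, MultiQC 1.7 and DESeq2 were used with genome build mm9; their order and settings are not given in the sources used here. The strand setting of the counting is not stated, so reads of overlapping antisense genes cannot be told apart. Reads of near-identical copies (ribosomal protein genes, globins, guanylate-binding proteins) are uncertain in the same way, because reads placed at several positions were left out of the gene counts.

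Each file lists 51826 genes by identifier only. Gene names and coordinates came from GENCODE vM1 on NCBIM37 (the assembly called mm9), matched on the identifier without its version. In all, 32708 identifiers had a name there, and they held 98.3% of the gene counts. The identifiers with their versions matched that table for 13979 genes only, since the files carry later versions than an mm9 annotation. A gene's limits during counting could therefore differ from the coordinates printed here, which are 1-based. Reads that HTSeq assigned to no gene made up 29.73% of reads on average (24.74% to 38.06% per library) and were left out of library sizes and tests. Gene counts per library ran from 21255934 to 51021670. Genes without an NCBIM37 name were tested but are not discussed by name, and results of some named genes are not reported here.

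The 39 libraries were grouped by title: 11 BLA and 10 NAc libraries of wild-type mice, and 9 BLA and 9 NAc libraries of Lmo4gt/+ mice. They came from 20 mice, of which 19 gave both regions. NAc library 122 carries the mutant name in its title and description and wild type in its genotype field; it was kept with the Lmo4gt/+ libraries, as its BLA counterpart is mutant in every field. The labels give no sex, litter, batch or date. Libraries of the 2 regions with the same number in their titles were taken to come from the same mouse: the numbers make 11 wild-type and 9 Lmo4gt/+ mice, the numbers of mice that the series' design text gives. The counts add little to this. Deviations from the group means correlated weakly between libraries of the same number (1 of 19 pairs over 0.1, and 5 of 19 highest with their own number; median Pearson's r across genes 0.0356 over 19 mice, against -0.00437 for different mice of the same genotype). No pair of libraries held identical counts. The lowest chi-square per degree of freedom of a pair within a group was 6.34, so none was a repeat of another.

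Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr with a minimum count of 10, robust glmQLFit, a two-sided quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Genotype was compared within each region. The region by genotype interaction (38 libraries) and the comparison of NAc with BLA in wild-type mice (20 libraries) kept the mouse as a block. All adjusted p-values for genes are from this edgeR test unless another tool is named. A ± beside a log2 fold change is its standard error, and a ± beside a level is the SD over libraries. Levels are CPM (counts scaled to a fixed library total), normalised with TMM factors. Intervals are at the 95% level; intervals and floors on read counts cover counting error only, as the reads carry no molecular identifiers, and a floor is 3 counts over the group named.

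Fixed gene lists, 33 in all, were written from general knowledge before the data were examined, as were the comparisons, the thresholds and the first set of alternatives. The lists cover cell types, transmitter systems, transcription factors and housekeeping machinery. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The symbols Gpr52, Slc18a3, Lhx8, Smim32, Lhfpl3, Hbb-bs, Hbb-bt, Ahsp and Gper1 had no match in the name table and were left out; Syndig1l is listed there as Tmem90a and was left out of its list. Overlap between lists of called genes used Fisher's exact test. Correlations across mice used permutation tests with 100000 resamples (SciPy 1.17.1, Python 3.11.15).

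The rule for named genes was also fixed beforehand. For each genotype comparison it takes Lmo4 and up to 10 called genes per direction. Genes with only an identifier, a Gm number, a Rik clone name or a pseudogene name are skipped in its rankings, except for the interaction. If fewer than 6 besides Lmo4 are called, it takes the 5 genes with the smallest p per direction and says that they did not pass. For the interaction it takes the 4 smallest p if fewer than 4 genes are called. For the regions it takes the 10 genes per direction with the largest change among genes with a mean of at least 20 CPM, and up to 4 called members per list by smallest p. Other genes named with a value, Gbp5 and members of lists in the genotype comparisons among them, were chosen after their values were seen.

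The steps were tested on simulated counts with 50 genes changed at each fold size. For the BLA comparison (16850 genes simulated), 68% of genes changed 1.5-fold and 82% of genes changed 2-fold were called. For the NAc comparison (16777 genes) the shares were 62% and 72%. For the interaction (18023 genes) they were 46% and 68%. For the region comparison (16394 genes) they were 64% and 80%. Of genes changed 1.25-fold, 46% were called for the BLA, 24% for the NAc, 8% for the interaction and 38% for the regions. False calls made up 4% of calls for the BLA, 3.8% for the NAc, 2.9% for the interaction and 6.8% for the regions. Each simulation held 200 changed genes, drawn independently and without structure among the samples. The real genotype fits called far fewer genes, which makes the adjustment of p stricter. For the regions, the real differences were taken out before the changes were planted. These shares may therefore be too favourable for the real data.

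The alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter of at least 1 CPM in at least 9 libraries, limma voom with sample quality weights, all 39 libraries in 1 model, no mouse block, each library or mouse left out in turn, and library 122 left out or counted as wild type. Covariates tried in turn were Xist, the first principal component of the cell type lists, and 1 surrogate variable (sva 3.50.0). The planned DESeq2 fits had no count filter besides DESeq2's own. Leaving out the libraries with the most RNA of another region or tissue, and DESeq2 with the count filter, were added after the data had been seen.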

Results

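LMO4 is a LIM-only protein that binds no DNA itself and links transcription factors to cofactors such as LDB1. The series, titled for the regulation of alcohol drinking and reward, compared wild-type mice with mice carrying a gene-trap allele (Lmo4gt/+) to look for genes under LMO4 control. RNA was counted in punches of the BLA, a nucleus rich in glutamatergic projection neurons, and of the NAc, a part of the ventral striatum made up mostly of GABAergic medium spiny neurons. The mice were 8 to 12 weeks old, on the C57BL/6J strain. BLA libraries came from 11 wild-type and 9 Lmo4gt/+ mice, and NAc libraries from 10 wild-type and 9 Lmo4gt/+ mice. Gene counts per library averaged 30589607 ± 5514921 (SD, n = 11) in wild-type BLA, 34293779 ± 7702101 (n = 9) in Lmo4gt/+ BLA, 27861723 ± 4341845 (n = 10) in wild-type NAc and 29850722 ± 7205254 (n = 9) in Lmo4gt/+ NAc. The Y-linked gene Uty was expressed in every library (at least 18 CPM), while Xist, the RNA of the inactive X chromosome, did not exceed 0.363 CPM in any.

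Lmo4 itself (ENSMUSG00000028266.17, chromosome 3, positions 143851494 to 143868184, minus strand, protein-coding, NCBIM37) was lower in Lmo4gt/+ mice in both regions. In the BLA it averaged 165 ± 9.55 CPM (SD, n = 11) in wild-type mice and 91.4 ± 12.9 CPM (n = 9) in Lmo4gt/+ mice, with ranges of 143 to 178 and 68.5 to 109 that did not overlap. The log2 fold change was -0.85 ± 0.06 (adjusted p = 2.82e-09), which left 55.4% of the wild-type level (95% interval 50.6% to 60.6%). In the NAc it averaged 86.5 ± 11.8 CPM (n = 10) in wild-type mice and 54 ± 8.89 CPM (n = 9) in Lmo4gt/+ mice, a log2 fold change of -0.68 ± 0.09 (adjusted p = 0.00214) that left 62.3% (54.7% to 71.1%). NAc library 122, whose labels conflict, held 69.7 CPM, the highest of the Lmo4gt/+ NAc libraries and above the lowest wild-type one (67.8 CPM). The sources used here do not place the trap within the gene, and these counts pool reads from both sides of it. The loss did not differ detectably between the regions (interaction log2 0.18 ± 0.13, edgeR p = 0.168, adjusted p = 1).

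**Figure D1:**
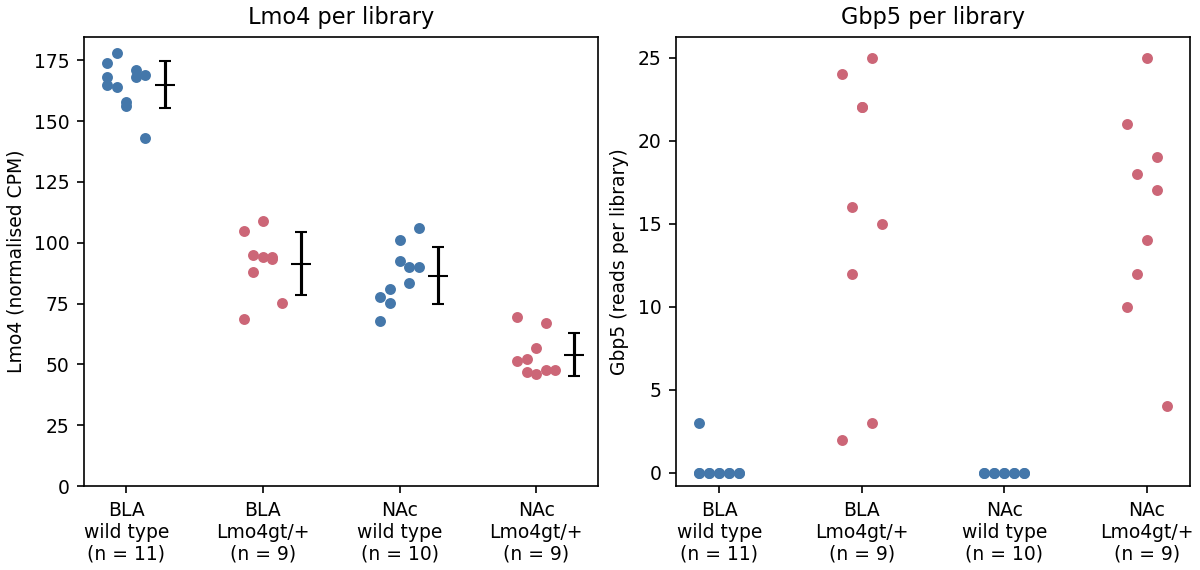
Left, Lmo4 in normalised CPM for each library by region and genotype; right, reads of Gbp5 per library. Points are libraries, and the black marks on the left are the mean and SD. Lmo4 lay between 143 and 178 CPM in wild-type BLA and between 68.5 and 109 CPM in Lmo4gt/+ BLA; Gbp5 had at least 2 reads in each Lmo4gt/+ library and none in wild-type NAc.

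In the BLA, Lmo4 was the only gene of 17087 tested that passed the threshold for a change with genotype. The genes next in rank under the naming rule, which skips unnamed genes, did not pass the threshold (adjusted p = 0.998 for each of the 10 named here). Toward higher values these were Nkx2-2, a homeobox factor of oligodendrocyte precursors (0.55 ± 0.14), Nfe2l2, the regulator of the antioxidant response (0.30 ± 0.08), Acacb, a mitochondrial acetyl-CoA carboxylase (0.52 ± 0.14), Npas1, a transcription factor of GABAergic neurons (0.33 ± 0.09), and Fbxw5, an F-box protein (0.15 ± 0.04). Toward lower values they were the heparan sulphatase Sulf2 (-0.20 ± 0.05), the kinase activator Mob3a (-0.35 ± 0.09), the mitochondrial transporter Abcb10 (-0.24 ± 0.06), Rai14 (-0.48 ± 0.12) and the zinc finger gene Zfp948 (-0.28 ± 0.08). At an unadjusted p under 0.05, 703 genes passed, 4.11% of those tested. For 92% of the genes the 95% interval excluded a change of 2-fold or more, and for 77.1% it excluded 1.5-fold.

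No fixed list had a member that passed in the BLA over all genes. Adjusted over the list alone, Htr3a, an ionotropic serotonin receptor of interneurons (0.41 ± 0.12), and Alas2, the haem synthesis enzyme of red cells (0.80 ± 0.23), were higher in Lmo4gt/+ mice. The microglial integrin Itgam (-0.36 ± 0.11) and the Y-linked demethylase Kdm5d (-0.17 ± 0.06) were lower on the same basis. With the first principal component of the cell type lists as a covariate, none of these 4 genes passed within its list (lowest adjusted p in the 4 lists 0.194, 0.0544, 0.129 and 0.0677), while 8 others did, among them Pde1b, Adcy5 and Gng7. Without library 127, Htr3a and Itgam did not pass (lowest adjusted p in their lists 0.0518 and 0.0837). Without libraries 129, 149, 156 and 159, only Htr3a of the 4 still passed. With camera at the preset correlation, 13 of the 33 lists were called, 4 toward higher and 9 toward lower values. Oligodendrocyte genes ranked lower in Lmo4gt/+ mice (median log2 fold change -0.14, 1 of 15 members above 0, adjusted p = 2.78e-06 with the preset correlation; adjusted p = 0.397 with an estimated correlation). The same held for mitochondrially encoded genes (median -0.14, adjusted p = 3.38e-07, and adjusted p = 0.365 with an estimated correlation). Opioid and stress neuropeptide genes, among them the mu opioid receptor Oprm1 (-0.36 ± 0.14) and the peptide gene Nts (-0.48 ± 0.18), had a median of -0.21 (adjusted p = 0.00215; adjusted p = 0.365 with an estimated correlation). Central amygdala and intercalated cell markers also had a median of -0.21 (adjusted p = 0.00215; adjusted p = 0.379 with an estimated correlation). The heat shock, immediate early, ribosomal protein, nuclear oxidative phosphorylation and sex-linked lists were the others toward lower values (adjusted p = 0.537, 0.573, 0.766, 0.766 and 0.378 with an estimated correlation). Toward higher values were meningeal fibroblast genes (10 of 10 above 0, median 0.45, adjusted p = 0.0182; adjusted p = 0.522 with an estimated correlation), oligodendrocyte precursor genes (9 of 9, median 0.04, adjusted p = 0.0317; adjusted p = 0.365 with an estimated correlation), astrocyte genes (11 of 14, median 0.03, adjusted p = 0.0338; adjusted p = 0.537 with an estimated correlation) and calcium handling genes (22 of 27, median 0.03, adjusted p = 0.0107; adjusted p = 0.537 with an estimated correlation). Markers of choroid plexus and ependyma (6 of 8 above 0, median 0.40, adjusted p = 0.886) and blood (5 of 6, median 0.31, adjusted p = 0.0861) lay toward higher values without being called. Lmo4gt/+ BLA library 127 held 38.3 CPM of the choroid plexus gene Clic6 and 65.4 CPM of Kl, against at most 14.2 and 13.8 CPM in wild-type BLA. Without it 9 lists were called, 8 of them among the 13. An ended call does not by itself show a smaller shift, since fewer libraries also weaken a test. The calls of the heat shock, immediate early, ribosomal protein, nuclear oxidative phosphorylation and astrocyte lists ended (adjusted p = 0.0616, 0.129, 0.0917, 0.129 and 0.0584), and those of the immediate early, nuclear oxidative phosphorylation, astrocyte and sex-linked lists ended without libraries 129, 149, 156 and 159 (adjusted p = 0.517, 0.208, 0.242 and 0.0765). Without library 127 the meningeal median was 0.36 (adjusted p = 0.0381; adjusted p = 0.544 with an estimated correlation), and choroid plexus and ependymal genes turned lower (median -0.51, adjusted p = 0.0306; adjusted p = 0.544 with an estimated correlation). With the same covariate as above, 9 of the 13 lists were called, some with smaller medians. These were -0.06 for oligodendrocyte genes (adjusted p = 0.0386), -0.09 for neuropeptide genes (adjusted p = 0.0207) and 0.27 for meningeal genes (adjusted p = 0.0282). With an estimated correlation their adjusted p was 0.62, 0.347 and 0.426. The calls that ended were those of central amygdala markers (median -0.07, adjusted p = 0.134), oligodendrocyte precursor genes (0.03, adjusted p = 0.0507), astrocyte genes and nuclear oxidative phosphorylation genes. Medium spiny neuron genes went from a median of -0.02 (adjusted p = 0.142) to 0.19 (adjusted p = 3.10e-09; adjusted p = 0.315 with an estimated correlation) with the covariate, 1 of 5 lists it added. Without BLA libraries 129, 149, 156 and 159 they were called the other way (median -0.12, adjusted p = 0.00422; adjusted p = 0.631 with an estimated correlation), so their direction is not settled. Without the covariate, no list was called with an estimated correlation, where adjusted p started at 0.365, or with fry, where it started at 0.265. With the covariate none was called either (adjusted p from 0.315 with an estimated correlation and from 0.488 with fry).

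In the NAc, Lmo4 was again the only gene that passed the threshold for a change with genotype, of 16999 tested. The ranking given here follows the same naming rule. Next in rank, none of them passing (adjusted p = 1 each), were the zinc finger gene Zfp951 (1.02 ± 0.23), the homeobox gene Emx2 (0.45 ± 0.13), Lmo1, a LIM-only relative of Lmo4 (0.54 ± 0.16), the connexin gene Gja5 (1.63 ± 0.49) and Myot, a sarcomere protein (1.89 ± 0.60), toward higher values. Toward lower values they were Nde1, which acts with dynein in neuronal migration (-0.43 ± 0.10), Ect2, an exchange factor of cell division (-1.21 ± 0.33), the RNA sensor Tlr3 (-0.35 ± 0.10), Cdc42ep2 (-0.48 ± 0.14) and the growth factor binding protein Igfbp5 (-0.40 ± 0.12). Gja5, Myot and Ect2, with the largest changes among these, were counted at low levels (average log2 CPM -0.226, -1.04 and -0.129). At an unadjusted p under 0.05, 454 genes passed, 2.67% of those tested. The 95% interval excluded 2-fold or more for 89.4% of genes and 1.5-fold for 73.3%.

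No member of a fixed list passed in the NAc over all genes. Adjusted over the list alone, Lmo1 was higher in the list of LMO4 partners and LIM-domain factors (adjusted p = 0.0463), and Aldh1a2, an enzyme that makes retinoic acid, was lower (-1.18 ± 0.35), both among alcohol and aldehyde metabolism genes and among meningeal fibroblast markers. Camera called 8 of the 33 lists with the preset correlation, 3 toward higher and 5 toward lower values. With the first principal component of the cell type lists as a covariate it called 5, of which 4 were among the 8; the glutamatergic list (median -1.04), the microglial list (-0.07), the dopamine signalling list (0.07) and the calcium handling list (0.04) had adjusted p from 0.0805 to 0.0917, and their calls ended without NAc libraries 122, 134 and 149 too. With the covariate, 10 oligodendrocyte genes, Mbp among them, passed over the list alone. Oligodendrocyte genes ranked lower in Lmo4gt/+ mice: all 15 had a negative fold change (median -0.26, adjusted p = 5.61e-09; adjusted p = 0.788 with an estimated correlation). The myelin gene Mbp among them was at -0.28 ± 0.15. Oligodendrocyte precursor genes had a median of -0.15 (adjusted p = 0.00216; adjusted p = 0.634 with an estimated correlation), with Olig2 at -0.21 ± 0.07. Medium spiny neuron genes ranked higher (median 0.12, 17 of 18 above 0, adjusted p = 0.00495; adjusted p = 0.788 with an estimated correlation). Alcohol and aldehyde metabolism genes had a median of -0.06, with Aldh1a1 at -0.54 ± 0.20 (adjusted p = 0.0103; adjusted p = 0.634 with an estimated correlation). Dopamine signalling (median 0.11) and calcium handling genes (0.07) ranked higher and microglial genes lower (-0.07; adjusted p = 0.788 for each of these 3 with an estimated correlation). Glutamatergic genes had a median of -0.53 (adjusted p = 0.0433, and adjusted p = 0.788 with an estimated correlation). NAc libraries of both genotypes held high outliers for them, described with the regions. The 17 NAc libraries besides 122 and 134 varied too: Slc17a7 had a median of 7.54 CPM and a maximum of 185 CPM among them. Its mean was 136 ± 281 CPM (SD, n = 10) in wild-type and 70.4 ± 173 CPM (n = 9) in Lmo4gt/+ NAc. That the call ended without libraries 122, 134 and 149 does not show that those libraries carried the shift. With the covariate the median was -1.04. No list was called in the NAc with an estimated correlation or with fry.

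Gbp5, an interferon-inducible guanylate-binding protein, was counted almost only in Lmo4gt/+ mice; it was singled out after its values had been seen. Its gene (ENSMUSG00000040264.10, chromosome 3, positions 142159864 to 142185308, plus strand, protein-coding) lies 1.67 Mb from Lmo4. In the BLA, all 9 Lmo4gt/+ libraries held Gbp5 reads (141 in total, 2 to 25 each), and 1 of the 11 wild-type libraries did (3 reads), a ratio of 51.2 (95% counting interval 17.2 to 251). In the NAc, all 9 Lmo4gt/+ libraries held reads (140 in total, 4 to 25 each) and none of the 10 wild-type libraries did. Against a floor of 3 counts over the wild-type group (0.0108 CPM), Gbp5 was at least 48.4-fold higher. The level stayed low, at 0.476 ± 0.28 CPM (SD, n = 9) in Lmo4gt/+ BLA and 0.514 ± 0.191 CPM (n = 9) in Lmo4gt/+ NAc, so the count filter removed it. Without the filter, with DESeq2 (run without that filter), and with all 39 libraries in 1 model, Gbp5 was called next to Lmo4 in both regions, which made 2 genes in each.

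The regions were then compared for the effect of genotype. In the separate edgeR fits with the count filter, Lmo4 was the only gene called in both. At an unadjusted p under 0.01, Lmo1 was shared among higher genes (52 in the BLA, 17 in the NAc, 0.0541 expected from independent lists, Fisher's exact p = 0.0527), and Lmo4 and Nde1 were shared among lower genes (52 and 33, 0.105 expected, Fisher's exact p = 0.00492). Lmo4 is the trapped gene and counts among the shared lower genes. That Fisher's p therefore does not measure a response of other genes common to both regions. Fisher's test takes genes as independent, which genes measured in the same mice are not: 16 of 100 reassignments of genotype over the mice, the real one included, shared at least as many as these 3. Lmo1 measured 4.98 ± 0.735 CPM (SD, n = 11) in wild-type and 6.49 ± 1.67 CPM (n = 9) in Lmo4gt/+ BLA. In the NAc it measured 4.51 ± 1.22 CPM (n = 10) and 6.56 ± 1.36 CPM (n = 9). Across 16351 genes other than Lmo4, the log2 fold changes of the regions had Pearson's r = 0.0378 and Spearman's rho = 0.0736; genes are not independent replicates, and the same mice stand behind both regions.

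For the test of a genotype effect that differs between regions, edgeR called 0 of 18325 genes, with 543 at an unadjusted p under 0.05. DESeq2 called 0 (835 at p under 0.05) and limma voom called 0 (831). The 4 genes ranked first, none of which passed, were 9030425E11Rik (0.48 ± 0.10), mt-Nd6, a complex I subunit encoded on the other strand of the mitochondrial genome from most of its genes (0.47 ± 0.10), Smoc1, a secreted calcium-binding protein (-0.74 ± 0.17), and Foxj1, the master regulator of motile cilia (-0.72 ± 0.17). Adjusted over the list alone, 4 genes passed: mt-Nd6 and the kappa opioid receptor Oprk1 (0.79 ± 0.22) with a more positive effect in the NAc, and the collagen gene Col1a1 (-0.85 ± 0.25) and Foxj1 with a more negative one. Oprk1 passed in the claustrum list and missed in the neuropeptide list (adjusted p = 0.0525). Without mice 122, 129, 134, 149, 156 and 159, only Col1a1 and Foxj1 still passed over the list alone, while all 4 did without mouse 127. Camera called 13 lists with the preset correlation, 6 toward more positive and 7 toward more negative effects, led by mitochondrially encoded genes (median 0.17, adjusted p = 1.08e-06; adjusted p = 0.174 with an estimated correlation) and meningeal fibroblast genes (median -0.45, adjusted p = 2.85e-05; adjusted p = 0.174 with an estimated correlation). For choroid plexus and ependymal genes the median (0.18) lay above 0 and the test below it (adjusted p = 0.0104; adjusted p = 0.347 with an estimated correlation). Without mouse 127, 8 lists were called, 7 of them among the 13, and the choroid plexus list was not (median 0.55, adjusted p = 0.386). None of the 13 held with an estimated correlation, and fry called none.

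The regions themselves differed widely in wild-type mice (n = 10 mice with both). Genes of medium spiny neurons rose in the NAc and genes of glutamatergic projection neurons fell. The largest rises were in Scn4b, a sodium channel subunit (5.39 ± 0.54), Gpr6 (4.76 ± 0.45), Tmem90a (4.35 ± 0.31), the dopamine receptor Drd2 (4.31 ± 0.45), the adenosine receptor Adora2a (4.26 ± 0.59), the G protein regulator Rgs9 (4.21 ± 0.28) and the dynorphin gene Pdyn (4.04 ± 0.34); Fam40b, Prkch and P2ry1 completed the 10. The largest falls were in the vesicular zinc transporter Slc30a3 (-6.45 ± 0.68), the vesicular glutamate transporter Slc17a7 (-6.24 ± 1.15), the synaptic protein C1ql3 (-6.13 ± 0.35), the transcription factor Bhlhe22 (-5.81 ± 0.24) and Cyp26b1, which degrades retinoic acid (-5.77 ± 0.27); Nrn1, Rtn4rl2, Nov, Prdm8 and Rspo2 completed the 10. In all, 10064 of 16887 genes passed, 5250 higher and 4814 lower in the NAc, of which 1147 and 1187 differed at least 2-fold. Lmo4 was itself lower in the NAc, at 52.3% of its BLA level (95% interval 47.5% to 57.7%, log2 -0.94 ± 0.07, adjusted p = 7.57e-09).

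All 18 medium spiny neuron genes rose in the NAc, for instance the retinoic acid receptor Rarb (3.27 ± 0.10) and the substance P gene Tac1 (3.55 ± 0.18). Of the D1 list, 7 of 9 rose, with Drd1a at 2.90 ± 0.16, and 1 fell; of the D2 list, 6 of 8 rose, with the enkephalin gene Penk at 3.31 ± 0.41, and 1 fell. Of 18 glutamatergic genes 17 fell, among them Etv1 (-2.11 ± 0.08) and the neurotrophin Bdnf (-5.25 ± 0.49). Of 5 cholinergic genes 4 rose, with choline acetyltransferase Chat at 5.17 ± 0.50. The interneuron list split: 6 of 17 rose, with the GABA synthesis enzyme Gad2 at 1.55 ± 0.11, and 9 fell, with Htr3a at -2.04 ± 0.13. Central amygdala markers also split, with 7 of 14 higher (Foxp2 at 2.72 ± 0.22) and 3 lower (Cyp26b1). Of 7 claustrum genes 3 rose and 4 fell, led by the nuclear receptor Nr2f2 (-5.02 ± 0.10). Counts adjusted over the list alone were equal for all of these lists. Camera called the medium spiny, D1, D2, glutamatergic and cholinergic lists (adjusted p = 1.32e-11, 0.0017, 0.0302, 4.92e-07 and 0.00711; adjusted p = 0.33, 0.33, 0.512, 0.367 and 0.33 with an estimated correlation). Over all 33 lists camera called 9 with the preset correlation and 0 with an estimated one. Fry, which tests whether the genes of a list move and does not compare them with other genes, called 23 lists for a change on balance one way (lowest adjusted p = 2.02e-07) and all 33 for a change in either direction.

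**Figure D2:**
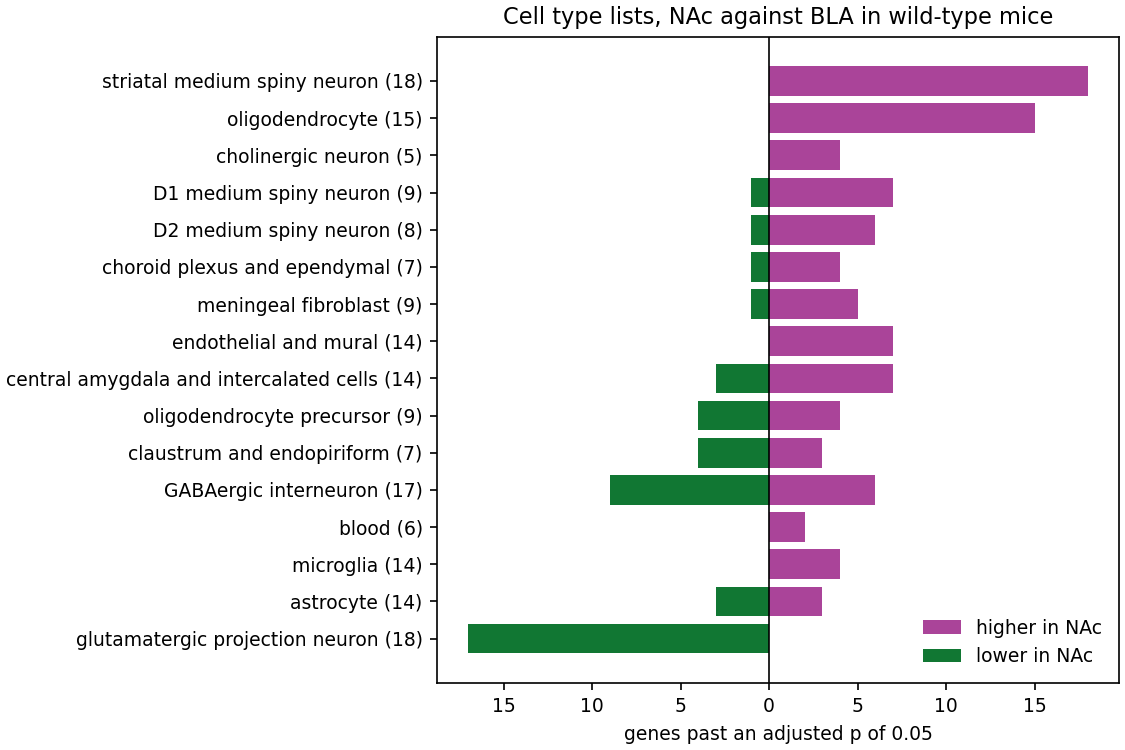
Number of genes of each fixed cell type list that passed an adjusted p of 0.05 between NAc and BLA in 10 wild-type mice; bars to the right count genes higher in the NAc and bars to the left genes lower there, with the number measured in brackets. All 18 medium spiny neuron genes and all 15 oligodendrocyte genes were higher, and 17 of 18 glutamatergic genes were lower.

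Among glia, all 15 oligodendrocyte genes rose in the NAc, with the myelin genes Mog at 1.55 ± 0.12 and Cnp at 1.45 ± 0.09 (camera adjusted p = 4.55e-09; adjusted p = 0.367 with an estimated correlation). Oligodendrocyte precursor genes went both ways (4 of 9 higher, with Olig2 at 0.53 ± 0.07, and 4 lower), as did astrocyte genes (3 of 14 higher, with Slc4a4 at 0.64 ± 0.05, and 3 lower, with the water channel Aqp4 at -0.55 ± 0.05). Of 14 microglial genes 4 rose over all genes and 1, the protease Ctss (0.29 ± 0.06), adjusted over the list alone. Of 14 endothelial and mural genes 7 rose, with Pdgfrb at 0.47 ± 0.05. Of 7 choroid plexus and ependymal genes 4 rose (Clic6 at 2.91 ± 0.33) and 1 fell; of 9 meningeal genes 5 rose (Igf2 at 0.47 ± 0.08) and 1 fell (Dcn at -2.75 ± 0.37). Of 6 blood genes 2 rose, with Hbb-b1 at 0.60 ± 0.20; that call ended without mouse 129, 156 or 160 (adjusted p = 0.0571, 0.0548 and 0.0541) and without the mouse block (adjusted p = 0.173). Except for microglia, counts adjusted over the list alone were equal.

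Of 18 dopamine signalling genes 15 rose in the NAc (16 adjusted over the list alone), including the G protein subunits Gng7 (2.85 ± 0.11) and Gnal (1.93 ± 0.10), and 1 fell (camera adjusted p = 2.03e-07; adjusted p = 0.33 with an estimated correlation). Of 9 endocannabinoid genes 7 fell, among them the anandamide synthesis enzyme Napepld (-1.77 ± 0.08) and the cannabinoid receptor Cnr1 (0.25 of its BLA level, adjusted p = 6.50e-10), and Mgll, which breaks down the ligand 2-AG, rose (0.56 ± 0.05; camera adjusted p = 0.0017; adjusted p = 0.33 with an estimated correlation). Opioid and stress neuropeptide genes split, 8 of 25 higher (9 adjusted over the list alone) and 11 lower, with Oprm1 at 1.69 ± 0.13 and the corticotropin-releasing hormone binding protein Crhbp at -3.22 ± 0.22. Glutamate receptors (8 of 24 higher, 13 lower) and GABA and glycine receptors (5 of 21 higher, 11 lower) also split; Grm4 was at 1.97 ± 0.12, Gria3 at -1.04 ± 0.07, the extrasynaptic GABA receptor subunit Gabrd at 2.31 ± 0.08 and Gabra3 at -2.08 ± 0.13. Of 18 LMO4 partners and LIM-domain factors 7 rose, with Lmo2 at 1.48 ± 0.10, and 7 fell, with Lmo3 at -1.29 ± 0.05 and the adaptor Ldb2 at -1.65 ± 0.09. Of 12 alcohol and aldehyde metabolism genes 4 rose, with the acetaldehyde-clearing enzyme Aldh2 at 0.71 ± 0.06, and 2 fell, with Acss2 at -0.67 ± 0.07. Counts adjusted over the list alone were equal where no other is given.

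Some libraries held RNA typical of the other region or of tissue nearby. Slc17a7 had a median of 12.5 CPM in wild-type NAc but reached 913 CPM in mouse 134, and a median of 7.54 CPM in Lmo4gt/+ NAc but 530 CPM in mouse 122. Among the other 17 NAc libraries it reached 185 CPM. In BLA libraries it lay at 1790 ± 122 CPM (SD, n = 11) in wild-type mice and 1830 ± 120 CPM (n = 9) in Lmo4gt/+ mice. Drd2 ran from 0.907 to 34.4 CPM in BLA libraries, against at least 91.6 CPM in the NAc.

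**Figure D3:**
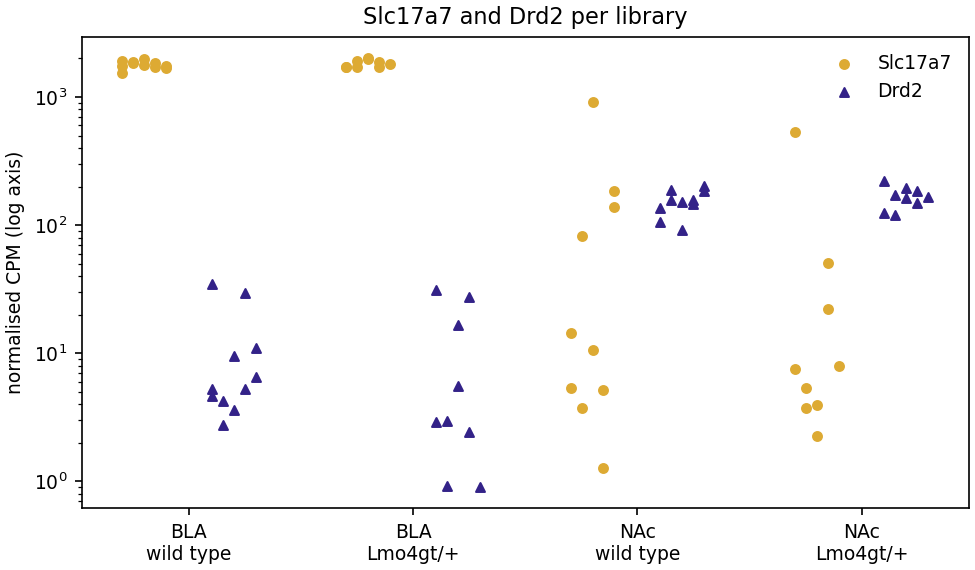
Slc17a7 (circles) and Drd2 (triangles) in normalised CPM on a log axis for each library by region and genotype. Slc17a7 reached 913 CPM in 1 wild-type NAc library and 530 CPM in 1 Lmo4gt/+ NAc library, against medians of 12.5 and 7.54 CPM.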

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

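The tests of NAc libraries 122 and 134 reported here were chosen only after the values had been seen. In groups of 4 to 10 libraries or mice, the highest or lowest value was checked against the gap to its neighbour with Dixon's test at the 95% level. Wild-type BLA, with 11 libraries, exceeds that size, so its levels were not checked as a group. Of 209 groups of values 15 stood out (7.18%), where chance gives about 1 in 20.

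Of these, 5 belonged to wild-type mouse 134, and all 5 lay toward a smaller difference between its NAc and BLA libraries. Its log2 NAc minus BLA value was -3.81 for C1ql3 (next mouse -5.52), -1.22 for Cck (-4.03), 0.51 for Grik2 (0.98), -0.75 for the GABA receptor gene Gabbr2 (-1.68) and 0.79 for the neurotrophic receptor gene Gfra1 (1.32). Other wild-type mice stood out once or more: mouse 160 for Drd1a (4, next 3.21) and Esr1 (-4.16, next -2.24), mouse 148 for Upb1 (7.46, next 4.42), and mouse 133 for Atp5d (-0.17, next -0.45) and Uty (-0.0869, next 0.18). Among Lmo4gt/+ libraries, BLA library 127 was highest for Acacb (11.2 CPM, next 6.6 CPM) and Foxj1 (6.28 CPM, next 2.97 CPM), and NAc library 157 was lowest for Emx2 (4.53 CPM, next 6.32 CPM). NAc library 149 had the lowest share of reads in genes (61.9%, next 66.7%) and the highest share outside them (27.6%, next 22.1%).

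NAc libraries 134 (wild type) and 122 (Lmo4gt/+) share a pattern: Slc17a7 stood at 51.1% and 29.7% of the BLA level, while the median medium spiny neuron level was 63.1% and 75% of that of the other 17 NAc libraries. RNA of the BLA sample of the same mouse, mixed in, is argued against. Such a mix lies between its sources, here the mouse's BLA library and the highest other NAc library. Yet 27 genes, Chrm3 and Ephb6 among them, lay over 1.5 times above both in both mice. The other 170 pairs gave at most 5, but they are no even yardstick. Each of them kept library 122, 134 or both among the libraries to exceed, and this pair was picked for its shared pattern. An earlier count restricted to the glutamatergic list found 1 such member. Other glutamatergic tissue in the punch stays open: 13 of the 17 list members besides Slc17a7 lay above every other NAc library in both, fewer than the 80% set for that explanation and more than the 50% set against it. No biological explanation was tested, since the pair spans both genotypes.

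The labels of NAc library 122 conflict, and its Lmo4 level (69.7 CPM) lay above the other Lmo4gt/+ NAc libraries (45.9 to 67.1 CPM). A wild-type sample under a mutant title is argued against by its 21 reads of Gbp5, inside the range of the other Lmo4gt/+ NAc libraries (4 to 25) and above the wild-type ones (0). Its distance from the fitted Lmo4 level fell from 2.27 to 1.27 residual SDs once the Slc17a7 level was a term, so glutamatergic tissue in the punch may account for part of it. The term was fitted on the other NAc libraries. Among these Slc17a7 stood at 913 CPM in library 134 and at most 185 CPM elsewhere, so the fit leans on library 134.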

How the results depend on the processing

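The alternatives were planned, except those that leave out libraries 122, 134 and 149 of the NAc or 129, 149, 156 and 159 of the BLA, those that leave out the same mice for the interaction and the regions, library or mouse 127 for the gene lists, DESeq2 with the count filter, and those near Lmo4 without the filter or at an unadjusted p, which were chosen after seeing the data. Lmo4 stayed lower and past the threshold in all 31 alternatives in the BLA (log2 -0.89 to -0.81, highest adjusted p 1.96e-07) and all 32 in the NAc (-0.74 to -0.65, highest adjusted p 0.0108). The counts of genes called in the BLA and in the NAc rose from 1 to 2 without the filter, with DESeq2 and with all 39 libraries in 1 model, each time by Gbp5, whose few reads the filter removes within a region but not over all 39 libraries. The planned DESeq2 fit had no such filter, so it changed the tool and the filter together; with DESeq2 and the filter 1 gene was called in each region and 1 in both. The other alternatives gave 1, and 1 with each library left out. The overlap between regions was 3 at an unadjusted p under 0.01, 2 with DESeq2 and 2 without the filter. Near Lmo4, 1 gene was called without the filter and 1 with DESeq2 without the filter in each region, and at an unadjusted p under 0.05 there were 3 in the BLA and 2 in the NAc. The count for the interaction stayed at 0 in every alternative, including the fit with no mouse block.

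With an estimated correlation, the number of gene lists called fell to 0 in the BLA, 0 in the NAc, 0 for the interaction and 0 for the regions. The first principal component of the cell type lists as a covariate gave 14 lists in the BLA (9 of the 13 and 5 others) and 5 in the NAc (4 of the 8 and 1 other); the covariate is built from the cell type lists among those tested, and the cause was not tested further. Of the genes that passed over the list alone, 0 of 4 did so with it in the BLA and 2 of 2 in the NAc; without library 127, 2 of 4 did in the BLA, and without 129, 149, 156 and 159, 1 of 4. For the interaction, 2 of 4 did without mice 122, 129, 134, 149, 156 and 159. Without the libraries with the most RNA of other tissue, 9 of the 13 lists in the BLA (without 129, 149, 156 and 159), 4 of the 8 in the NAc, 10 of the 13 for the interaction and all 9 for the regions were still called. In the BLA the medium spiny neuron, D2 and dopamine signalling lists were then called toward lower values (median -0.12, -0.19 and -0.06, with adjusted p = 0.00422, 0.025 and 0.0227), opposite to their calls with the covariate (0.19, 0.18 and 0.14). None of these calls held with an estimated correlation in either setting (adjusted p = 0.315 for each list with the covariate). Gained in the NAc were blood and meningeal genes, for the interaction blood and central amygdala markers, and for the regions nuclear oxidative phosphorylation genes. Without mouse 127 the interaction had 8 lists (7 of the 13). For the regions, fry called 23 lists, against 9 with camera and 0 with camera at an estimated correlation. For the regions, calls ran from 9548 to 10933 over the alternatives: 10123 without the filter (9255 shared with the 10064), 10933 with DESeq2 (9731 shared), 9900 with no mouse block (9642 shared) and 9548 without mice 129, 134 and 156 (9101 shared). Leaving out each mouse gave 9589 to 10077. The pairing changed no other count, and of the named genes it ended the call of Hbb-b1 only (log2 0.47, adjusted p = 0.173 with no block, 0.0541 to 0.118 in the other alternatives that ended it). Over the named genes, 3260 combinations with an alternative kept their direction and side of the threshold, 0 reversed and 26 fell short of it, all for the regions, those of C1qb, C1qc, Hbb-b1 and Eif2s3y among them, whose fold changes are small or vary between mice. Low counts kept Gbp5 out of the fits of each region with the filter. The precision of the genotype results rests on depth and on the spread between libraries (common biological coefficient of variation 0.161 in the BLA and 0.229 in the NAc), which were not separated: the 95% interval excluded a change of 1.5-fold or more for 77.1% of genes in the BLA and 73.3% in the NAc.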

Other observations

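The tests of Gbp5, of list levels across mice and of the combined change in both regions, and the splits for Lmo4's fold change, for the gene lists and for genes at an unadjusted p, were chosen only after the results had been seen. The planned tests here are those of the gene lists between regions, the test of genes near Lmo4 and the splits for the counts of genes and for their overlap.

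Further gene groups differed between NAc and BLA in wild-type mice (n = 10). Cytosolic ribosomal protein genes were higher in the NAc for 66 of 80 members (67 adjusted over the list alone), with Rpsa at 0.69 ± 0.05, and 3 were lower (camera adjusted p = 5.15e-09; adjusted p = 0.62 with an estimated correlation); processed copies make single members uncertain. Nuclear oxidative phosphorylation genes were lower for 32 of 76 (30 adjusted over the list alone) and higher for 7 (6 adjusted over the list alone), with the ATP synthase subunit Atp5d at -0.50 ± 0.04. Mitochondrially encoded genes were higher for 8 of 22, with mt-Cytb at 0.34 ± 0.05, and lower for 1. Heat shock and unfolded protein response genes were lower for 10 of 20, with the chaperone Hsp90aa1 at -0.80 ± 0.05, and higher for 4. Of 20 immediate early genes 6 were lower, with Nr4a3 at -1.68 ± 0.15 and Jun at -1.32 ± 0.14, and 2 were higher (1 adjusted over the list alone).

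Ion channel and receptor genes split by member. Of 29 potassium channel genes 10 were higher, with Kcna4 at 1.64 ± 0.10 and Kcnk2 at 1.60 ± 0.09, and 16 were lower. Of 27 calcium handling genes 10 were higher (11 adjusted over the list alone), with the store sensor Stim1 at 0.58 ± 0.05, and 12 were lower, with the plasma membrane pump Atp2b4 at -1.09 ± 0.06. Of 14 ALK and neurotrophin genes 5 were higher, with Gfra1 2.82-fold higher, and 8 were lower, with Ltk at -1.30 ± 0.17. Of 12 oestrogen and steroid receptor genes 3 were higher, with the glucocorticoid-induced kinase Sgk1 at 1.10 ± 0.15, and 3 were lower, with the oestrogen receptors Esr1 (-1.86 ± 0.25) and Esr2 (-3.51 ± 0.51). Of 5 sex-linked genes 4 were higher, with the Y-linked Kdm5d at 0.55 ± 0.05. Counts adjusted over the list alone were equal except where given.

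Gbp5 was the only one of 33937 genes with a read that was seen in at least 16 of the 18 Lmo4gt/+ libraries and in at most 2 of the 21 wild-type ones, or the reverse. Reads of the paralogs Gbp2, Gbp3 and Gbp7 counted as Gbp5 at a constant rate are argued against: Gbp5 made up 0.0834% of the reads of the 4 genes in wild-type and 5.33% in Lmo4gt/+ BLA (permutation p = 4e-05), and 0% and 4.59% in the NAc (permutation p = 2e-05). A response to 1 level of Lmo4 RNA common to both regions could not be decided. Lmo4gt/+ BLA, with Gbp5 reads in all 9 libraries, averaged 1.06 times the counted Lmo4 of wild-type NAc, with none (exact permutation p = 0.396). All 9 lay above the lowest wild-type NAc library. Those counts pool reads from both sides of the trap and come from punches of different cells. Levels of intact Lmo4 RNA per cell could therefore differ. A response within each region to its own loss of Lmo4 stays open. An effect tied to the locus, by donor-strain DNA beside the trap or by the trap itself, stays open and could not be tested. Without the count filter, Gbp5 was the only called gene besides Lmo4 (1 of 118 genes within 10 Mb of Lmo4 against 0 of 23076 elsewhere in the BLA, and 1 of 113 against 0 of 22773 in the NAc), so Fisher's exact p (0.00509 and 0.00494) only restates where that gene lies. The design cannot separate those sources from loss of LMO4, and neighbours were not enriched at an unadjusted p under 0.05 (3 of 73 against 4.09% elsewhere in the BLA, Fisher's exact p = 1, and 2 of 73 against 2.52% in the NAc, p = 0.707).

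The planned test of called genes within 10 Mb of Lmo4, with the count filter, had no called gene besides Lmo4 to place and could show nothing (Fisher's exact p = 1 in the BLA and p = 1 in the NAc). A signed combination of both regions' p-values over 16352 genes passed Lmo4 (adjusted p = 5.75e-15) and no other gene; Nde1 came next (adjusted p = 0.0537; -0.27 ± 0.09 in the BLA and -0.43 ± 0.10 in the NAc), then Lmo1 (adjusted p = 0.312). Reassigning genotype over the mice gave at least 1 gene in this test in 11 of 100 draws, the real one included, and up to 183.

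The genotype results were set against other splits of the same libraries, with the real split counted among them. As many genes as the real 1 were called in 6 of 100 splits of the BLA libraries, with 35 as the highest of the others, so chance is not excluded for the count alone. The size of Lmo4's BLA change was reached by 1 of 100, the real split (0.85 on the log2 scale, highest other 0.50), so no other split drawn reached it. In the NAc, 2 of 100 splits called as many (highest other 1), a share below 0.05. Lmo4's change there was reached by 1 of 100, the real split (0.68, highest other 0.51). Called in both regions the same way, 1 gene was reached by 1 of 100 reassignments, the real one (highest other 0). That gene is Lmo4, so the overlap restates its fall in each region and shows no response common to other genes. With 100 draws, no share below 1 in 100 can be shown. For the interaction, all 40 of 40 reassignments gave at least the real 0 (highest other 2), so its count says nothing against chance. At an unadjusted p under 0.05, as many genes passed in 43 of 100 splits in the BLA (real 703, highest other 2933), 81 of 100 in the NAc (real 454, highest other 2633) and 24 of 40 for the interaction (real 543, highest other 1648). The 3 genes shared by both regions at an unadjusted p under 0.01, Lmo4 among them, were matched in 16 of 100 reassignments (highest other 18). Chance is not excluded for any of these 4 counts. Splits that called 35 or 183 genes, far more than the real 1, point to a structure of the samples that was not tested, as the labels give no batch, litter or date.

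Exchanging regions within mice gave as many genes as the real 10064 in 1 of 100 draws, the real one (highest other 7173). The draws with 6376 and 7173 calls had 1 and 9 of the 10 mice exchanged and so nearly matched the real or the mirrored design. For the gene lists with the preset correlation, as many calls came up in 9 of 100 splits in the BLA (real 13, highest other 15), 44 of 100 in the NAc (real 8, highest other 16), 6 of 40 for the interaction (real 13, highest other 16) and 30 of 100 for the regions (real 9, highest other 14). Chance is thus not excluded for these counts in the BLA, in the NAc and for the interaction. For the regions the count of lists cannot decide. Other draws matched it although all 18 medium spiny and all 15 oligodendrocyte genes passed individually.

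Immediate early genes deviated together in the BLA and NAc of a mouse: across 19 mice, Pearson's r was 0.664 (permutation p = 0.00194, adjusted p = 0.032 over 33 lists) and Spearman's rho 0.533 (permutation p = 0.0201, adjusted p = 0.332). Without mice 159 and 160, the farthest from the median, r was 0.296 (permutation p = 0.25), so the relation rests on those mice and a state shared by both regions can be neither excluded nor shown. Heat shock genes gave r = 0.697 (permutation p = 0.00149, adjusted p = 0.032) and rho = 0.419 (permutation p = 0.0748, adjusted p = 0.35), with r = 0.325 (permutation p = 0.202) without mice 134 and 138. Claustrum genes went opposite ways in the regions of a mouse (r = -0.642, permutation p = 0.00308, adjusted p = 0.0339; rho = -0.584, permutation p = 0.00942, adjusted p = 0.311), with r = -0.534 (permutation p = 0.029) without mice 156 and 160.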
